A study of Triticum aestivum with 9 samples.

How the data were processed

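Gene expression was measured on 9 Affymetrix wheat arrays, 1 per sample. Seedlings of Avocet*6/Yr1, a wheat (Triticum aestivum) line that carries the yellow rust resistance gene Yr1, were 14 days old at inoculation. Per the labels' protocols, each sample was leaf RNA pooled from 5 time points (6, 12, 24, 48 and 72 hours after inoculation, 16 µg of RNA per time point). RNA was extracted with Trizol, cleaned with RNeasy columns and labelled with biotin. The pooling leaves 1 value per gene for the whole course, so no time course was analysed here.

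The deposited values are linear signal intensity values, 1 per probe set and array, and the submitters' processing notes name MAS5, whose version is not given in the sources used here. MAS5 is an Affymetrix method that summarises the probes of a probe set on each array separately. The 2% trimmed mean of the deposited intensity was 500.2 on every array, so the arrays had been scaled to a common mean before deposit. No detection calls were used here, and values near the background were handled only by a filter on mean intensity. No column of the table was left unused.

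The table held 61290 probe sets, of which 111 were controls of the array and 61179 were not. Intensities were raised to at least 1 and converted to log2, and 504 of 550611 values lay at or below that floor. Probe sets were kept when their mean log2 intensity over all 9 arrays reached the 40th percentile (6.35, an intensity of 81.7), which left 36707 for testing. No further normalization was applied in the main analysis, since the authors' values were already scaled.

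Groups came from the labels, with 3 arrays each for mock, avirulent and virulent inoculation. A linear model with 3 group means was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend (6 residual degrees of freedom, 5.12 prior degrees of freedom). The 3 pairwise differences and an F test over the 3 groups were taken from this fit. P-values were two-sided and were adjusted by Benjamini-Hochberg over the 36707 probe sets within each difference, and a probe set was called at an adjusted p under 0.05. Fold changes are 2 to the power of differences of mean log2 intensity. Nothing in the labels says whether replicates came from separate plants or inoculations, so p-values measure the spread between these samples, which may be technical. For arrays, the number of arrays limits the precision.

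Gene names came from the array's annotation table, in which 1273 probe sets had exactly 1 symbol, 0 had several and 59906 non-control probe sets had none. These stood for 771 genes. Names were updated through the Entrez number with a gene table of the assembly IWGSC CS RefSeq v2.1, which matched 1272 of them; its coordinates were not used because no genome build is named for the array. Of the tested probe sets, 960 (2.62%) had a gene, from 632 genes. Most symbols were gene numbers beginning with LOC, and only 135 tested probe sets had a symbol or synonym of another kind. Probe sets listed without a gene are unnamed here, and the text describes at most 2 of them per direction and comparison.

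Before the data were examined, 18 gene lists had been written as word patterns on gene descriptions. The tables gave no descriptions, so 11 of those lists had no member and 0 reached the 5 tested probe sets set as the minimum for a set test. A further 9 lists were therefore made from gene symbols and synonyms, after the names but not the comparisons had been seen, and 7 of them had at least 5 tested probe sets. Lists were tested with camera in limma, with a preset correlation of 0.01 between genes and adjustment over the 7 lists within a comparison. For list members, a count of calls adjusted over the list alone is given beside that over all probe sets. The adjustment over the list alone does not allow for the number of lists or comparisons.

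The rule for the genes the text names was written before the data were examined. It takes, per comparison, up to 10 rises and 10 falls among called probe sets with 1 named gene and no overlap between the groups, 1 probe set per gene. It adds up to 2 called members per direction of each list, or the member with the smallest p where none was called, and up to 2 called unnamed probe sets per direction. Where fewer than 6 named probe sets passed, the 10 named ones with the smallest unadjusted p were listed too and are said not to pass.

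Alternatives set before the data were examined were no filter and a filter at the 60th percentile, quantile normalization, median centring, an offset of 26.9 added before log2, no intensity trend, robust moderation, array weights, fits of only the groups compared, the replicate number as a block, each replicate left out, a 2-fold minimum, an adjusted p under 0.10 and adjustment over the 3 comparisons together. For the lists they were an estimated correlation, fry, 1 probe set per gene, no filter, quantile normalization and the block. Added after seeing the data were the 3′ to 5′ difference of sucrose synthase and that of G-6-PDH, each as a covariate, leaving out the 3 arrays with the highest such difference, a blocked fit of only the mock and avirulent arrays, and, for the lists, median centring and each replicate left out.

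The groups share replicate numbers in the labels, so it was checked whether arrays of one number deviated together from their group means. The correlations between mock and avirulent arrays of the same number were 0.12, 0.19 and 0.39, all above the limit of 0.1 set for treating the numbers as pairs. Those with the virulent arrays lay between -0.12 and 0.06 for mock and between -0.18 and 0.06 for avirulent, below that limit. Some arrays of different numbers deviated together too: mock 2 and avirulent 1 had 0.19, and avirulent 3 and virulent 2 had 0.20. The other pairs of different numbers lay between -0.31 and 0.05 for mock with avirulent, and between -0.07 and 0.15 with virulent arrays. These values alone cannot tell a pairing by number from another structure that crosses the groups. With the replicate number as a block, 24 probe sets were called between avirulent and mock arrays, 17 of them among the 21 called without it.

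The fit was tested on simulated data with the means and spreads of the 36707 probe sets in 10 runs, with 200 probe sets changed per run in the comparison of avirulent with mock. Of 100 changed 2-fold per run, 35.8% were called on average, and of 100 changed 4-fold, 80.6%. Unchanged probe sets made up 7.03% of the calls. A list of 30 probe sets shifted by 0.3 on the log2 scale was called in all 10 runs, and 0 of 200 unshifted lists were. Probe sets were drawn independently in these runs. The list counts therefore cannot tell how often lists with correlated members, such as several probe sets of the same gene, are called falsely. The exact permutation tests were run in Python 3.11.15 with numpy 2.4.6, and the figures were drawn with matplotlib 3.10.9.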

Results

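Transcript levels were compared in leaves of wheat seedlings carrying Yr1 after 3 inoculations. Wheat yellow rust is a leaf disease caused by a rust fungus, and a resistance gene such as Yr1 stops those isolates that it recognises. One group received an isolate that is avirulent on Yr1 and gives an incompatible interaction. Another received an isolate that is virulent on Yr1 and gives a compatible interaction, and the mock group received talcum powder. Each group had 3 arrays, and each array read RNA pooled from 5 time points up to 72 hours.

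All 9 arrays had the same scaled mean, and their median intensity lay between 122 (virulent 1) and 161 (avirulent 1). Correlations of log2 intensity were 0.931 to 0.954 between arrays of 1 group and 0.923 to 0.957 between arrays of different groups, so the groups overlapped at the level of whole arrays. The control probe sets for sucrose synthase read the 3′ end of the transcript above the 5′ end on every array, a measure of RNA integrity and labelling. The 3′ to 5′ ratio was 15.2 on mock 2, 12.5 on avirulent 2 and 15.2 on virulent 3, against 7.58 to 9.76 on the other 6 arrays. By this control each group held 1 array with a high ratio. The controls for the enzyme G-6-PDH split otherwise: the log2 difference between 3′ and 5′ end was 0.60 to 0.85 on the mock arrays, 0.61 to 1.14 on the avirulent arrays and 1.07 to 1.61 on the virulent arrays, so that each virulent array lay above each mock array. The 5′ control probe set was lower in the virulent than in the mock arrays (log2 fold change -0.55, limma unadjusted p = 0.0064, adjusted p = 0.13 over 20 controls).

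The avirulent isolate was compared with mock to find the transcripts that change in the incompatible interaction. All 21 probe sets called were higher in the avirulent arrays, by 1.87-fold to 12.9-fold, and 0 were lower. LOC543422 rose from an intensity of 428 ± 79.7 in mock to 2728 ± 897 in avirulent arrays (SD, n = 3 each), 6.24-fold (log2 fold change 2.64, SE 0.22, limma adjusted p = 0.0044). LOC543342 rose 7.06-fold, from 267 ± 107 to 1829 ± 534 (adjusted p = 0.011). LOC543313 rose 2.62-fold, from 618 ± 118 to 1609 ± 200 (adjusted p = 0.028).

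A second tested probe set of LOC543422 rose too (log2 fold change 2.58, adjusted p = 0.045), a call that was lost with the replicate number as a block on all arrays (adjusted p = 0.060). The other probe set of LOC543342 did not follow the first, with a log2 fold change of -0.06 (unadjusted p = 0.77 in limma). The tables name these 3 genes by number only, without a description of the protein. The probe sets with the largest rises were unnamed: the first rose 12.9-fold, from 90 ± 51 to 1060 ± 253, and the next 8.46-fold, from 55 ± 21 to 473 ± 200. In each of the 21 probe sets, all 3 avirulent arrays lay above all 3 mock arrays, a separation that chance gives for 10% of probe sets and that 9.90% of all tested ones showed in either direction. An unadjusted p under 0.05 was found for 1583 probe sets, fewer than the 1835 expected by chance of independent arrays. The other 9 splits of these 6 arrays gave 525 to 4788. These fits leave out any pairing of mock and avirulent arrays by number, so 1835 is no exact expectation. The other splits that part all same-numbered arrays gave 590, 1359 and 525, all below the real split. The 4788 came from a split that put mock 3 and avirulent 3 together.

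PR5 (LOC543292), a pathogenesis-related protein of the thaumatin-like family, had an intensity of 296 ± 257 in mock and 2810 ± 1316 in avirulent arrays. Its log2 fold change of 3.52 (SE 0.53) missed the threshold over all probe sets (adjusted p = 0.053). With the replicate number as a block it passed (adjusted p = 0.016), and over 23 alternatives its adjusted p ranged from 0.0029 to 0.26. It was the 1 of 5 probe sets of the defence protein list that passed when adjusted over the list alone. The other members of that list, a xylanase inhibitor (XIP-I), a serpin (SER1) and a lectin (WGA2), had log2 fold changes between -0.14 and 0.06. Next to the called genes stood LOC543234 (log2 fold change 2.59, adjusted p = 0.051), LOC543369 (2.13, adjusted p = 0.067) and LOC543363 (1.19, adjusted p = 0.070), followed by LOC543492 (1.46), LOC543330 (3.35) and LOC543233 (2.76). These 7 genes, PR5 included, did not pass, with adjusted p from 0.051 to 0.121, although in all of them the avirulent arrays lay above the mock arrays. With the block LOC543369 passed too (adjusted p = 0.043, range 0.0034 to 0.38), and LOC543234 passed with the block on the mock and avirulent arrays alone (adjusted p = 0.043, range 0.00021 to 0.24).

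No gene list was called between avirulent and mock arrays, except for tubulins in 1 alternative, in which each gene had 1 probe set (6 probe sets, mean log2 fold change -0.18, adjusted p = 0.034, range over 19 alternatives 0.034 to 0.99). With all probe sets the adjusted p over 7 lists was 0.41 for defence proteins (5 probe sets, mean log2 fold change 0.65, median -0.08), 0.34 for redox enzymes (12, mean -0.09) and 0.83 for photosynthesis genes (26, mean 0.02). It was 0.83 for histones (14, mean -0.04), 0.43 for tubulins (10, mean -0.0040), 0.43 for translation genes (8, mean -0.08) and 0.34 for seed storage genes (7, mean -0.19). In the last list the members BMY1 and ALPb-4A1 had mean intensities of 2907 and 4895 on the mock arrays. The list as a whole was therefore not read as a marker of another organ. Whether these signals come from the named genes was not checked. In each list the member with the smallest p did not pass over all probe sets: these were the alpha-tubulin TUBA (0.83, adjusted p = 0.89, with its other probe set at -0.16), BMY1 (LOC543318, -1.01), the histone wcH2B-6 (LOC543183, -1.21, the other probe set at 0.11), RPL9 (LOC543077, -0.53), TaPrx1 (LOC606328, -0.24), rbcl (LOC100049018, 0.22), the glutathione transferase GSTZ1 (LOC543412, -0.31), the initiation factor eIF4E (LOC543485, -0.17), EM (LOC543497, 0.43) and 6-FEH (LOC780575, 0.28). Lists under 5 probe sets had no set test, and 0 members passed in the fructan exohydrolases (4 probe sets, mean 0.14), the dehydration genes EM and Rab15 (2, mean 0.00), and the fixed lists of redox and detoxification (4, mean 0.03) and of translation (3, mean -0.08).

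The count of 21 moved with single arrays: it was 6 without mock 1, 63 without mock 2, 1 without mock 3, 10, 8 and 7 without avirulent 1, 2 and 3, and 12 without virulent 1. It was 82 without the 3 arrays of high sucrose synthase ratio, 0 without the intensity trend, and 46 in a fit of the mock and avirulent arrays alone with the replicate number as a block. With the block on all 9 arrays 24 were called: 17 of the 21 kept their call, 4 lost it (adjusted p from 0.060 to 0.074) and 7 others gained one. In fits of the 6 arrays alone, 9 were called without the block and 46 with it, 8 and 18 of them among the 21. The calls were not all in 1 direction in some fits: 14 of the 46 with that block were lower in the avirulent arrays, 16 of the 82 without the 3 arrays, 1 of the 63 without mock 2, 2 of the 8 without avirulent 2 and 3 of the 25 without virulent 3.

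**Figure D1:**
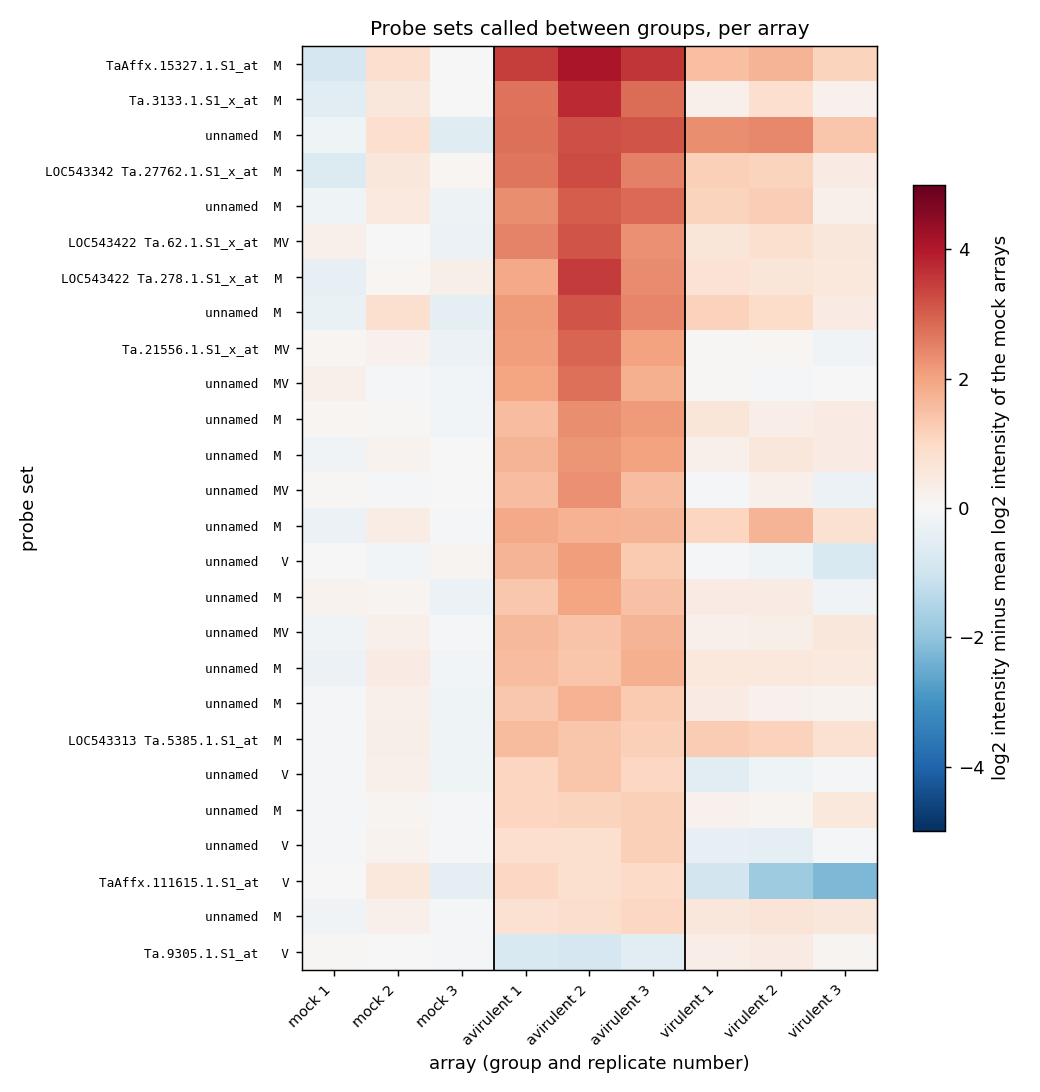
Heat map of the 26 probe sets called between avirulent and mock (M) or between avirulent and virulent arrays (V). Rows are probe sets, with the identifiers of named genes and of the unnamed probe sets described in the text, columns are the 9 arrays, and colour is log2 intensity minus the mean log2 intensity of the 3 mock arrays. The 21 rows marked M are raised in all 3 avirulent arrays.

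The virulent isolate was compared with mock to find the transcripts that change in the compatible interaction. No probe set was called with limma (smallest adjusted p = 0.238), while 3771 had an unadjusted p under 0.05, against 1835 expected by chance and 571 to 2916 in the other 9 splits of these 6 arrays. Of the 10 named genes with the smallest p, 9 were higher and 1 was lower in the virulent arrays, and none passed. LOC543369 had an intensity of 290 ± 162 in mock and 1289 ± 200 in virulent arrays, a log2 fold change of 2.27 (SE 0.34, adjusted p = 0.238), close to its 1199 ± 390 in avirulent arrays. LOC542814 (log2 fold change 0.83), LOC542934 (0.75), LOC542773 (1.92), LOC542857 (1.41), LOC780664 (0.63), LOC543123 (1.59) and LOC543085 (1.58) were higher without passing, and so was LOC543313 (1.07), which was called in the avirulent arrays. The 1 lower gene was rbcl, the large subunit of Rubisco, through 1 of its probe sets (-0.94).

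The photosynthesis list fell in the virulent arrays, with 21 of 26 probe sets below 0 and a mean log2 fold change of -0.26 (camera, adjusted p = 0.0035 over 7 lists). The call was lost with an estimated correlation (adjusted p = 0.51), and the adjusted p ranged from 0.00044 to 0.51 over 19 alternatives. The G-6-PDH difference between 3′ and 5′ end moved with these groups, at 1.07 to 1.61 on the virulent and 0.60 to 0.85 on the mock arrays, and with it as a covariate the list mean was -0.053 and the call was lost (adjusted p = 0.086). Since the difference moved with the groups, that fit cannot tell its part from that of the inoculation. Within groups 0 probe sets followed the difference at a limma adjusted p under 0.05. At an unadjusted p under 0.05 there were 2249, against 1835 expected by chance. Of the 26 probe sets, 19 read the 1 gene rbcl. The other 7 read 5 genes: phosphoribulokinase (PRK), the oxygen-evolving proteins PsbO and PsbP, the Rieske protein petC, and fructose-bisphosphatase (FBP), with 6 of 7 below 0 (mean -0.06). Those 6 lay between -0.27 and -0.18, and the mean was raised by 1 probe set of FBP at 0.98 (limma unadjusted p = 0.22). With 1 probe set per gene the list mean was -0.20 and the call stayed (camera, adjusted p = 0.0095). Quantile normalization kept the direction but not the call (mean -0.17, adjusted p = 0.18), and so did leaving out virulent 2 (mean -0.17, adjusted p = 0.13) or mock 2 (mean -0.14, adjusted p = 0.056). Without the 3 arrays of high sucrose synthase ratio the mean was -0.24 (adjusted p = 0.022). Median centring moved the median of all tested probe sets by 0.14, and the list then had a mean of -0.12 (adjusted p = 0.011).

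The 4 probe sets of the fructan exohydrolases, enzymes that break down stored fructan, were all higher in the virulent arrays, on which the G-6-PDH difference was also higher (1.07 to 1.61 against 0.60 to 0.85), with a mean log2 fold change of 0.86. In this comparison 3771 of the 36707 tested probe sets had a limma unadjusted p under 0.05, against 1835 expected by chance. All 4 list members passed when adjusted over the list alone, which does not allow for the number of lists. Over all probe sets 0 of these 4 passed. They read only 2 genes, and all but 1 of them read 6-FEH, the last being 1-FEH. The 6-FEH (LOC780575) probe set with the smallest p went from 278 ± 204 in mock to 609 ± 121 in virulent arrays (1.35, adjusted p = 0.33), with mock 2 at 513 against 145 and 178 on the other mock arrays. No other list was called with the settings given above: adjusted p was 0.83 for defence proteins (mean 0.03, median -0.05), where PR5 had a log2 fold change of 1.37 (adjusted p = 0.42), and 0.16 for redox enzymes (mean -0.15), of which 2 of 12 passed over the list alone. It was 0.12 for histones (mean -0.30, 13 of 14 below 0), 0.22 for tubulins (0.13), 0.59 for translation genes (-0.27, median 0.00) and 0.41 for seed storage genes (-0.11). In alternatives, histones were called lower after median centring (mean -0.17, adjusted p = 0.045, range over 18 alternatives 0.045 to 0.87), though their mean was 0.020 with the G-6-PDH covariate. Tubulins were called higher without mock 2 (0.25, adjusted p = 0.048, range over 19 alternatives 0.048 to 0.87), and redox enzymes lower without virulent 3 (-0.22, adjusted p = 0.036) and with the G-6-PDH covariate (-0.31, adjusted p = 0.0064, range over 19 alternatives 0.0064 to 0.51). Means were 0.19 for redox and detoxification, -0.06 for the fixed translation list and -0.12 for the dehydration genes, with 0 members passing. The members with the smallest p, none past the threshold over all probe sets, were GSTZ1 (0.28), eIF4E (-0.23), TaPrx1 (-0.47), the histone wcH2A-9 (LOC732714, -0.88, its others at -0.11 and -0.10), TUBA (0.84, the other at 0.08), RPS29 (LOC606342, -1.76, the other at 0.0021), Rab15 (LOC543293, -0.31) and ALPb-4A1 (LOC100125692, -0.26).

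The count of 0 moved with 2 arrays, both of high sucrose synthase ratio: 190 probe sets were called without mock 2 and 165 without virulent 3, and 0 without any other single array. Without the 3 arrays of high ratio, 321 were called.

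**Figure D2:**
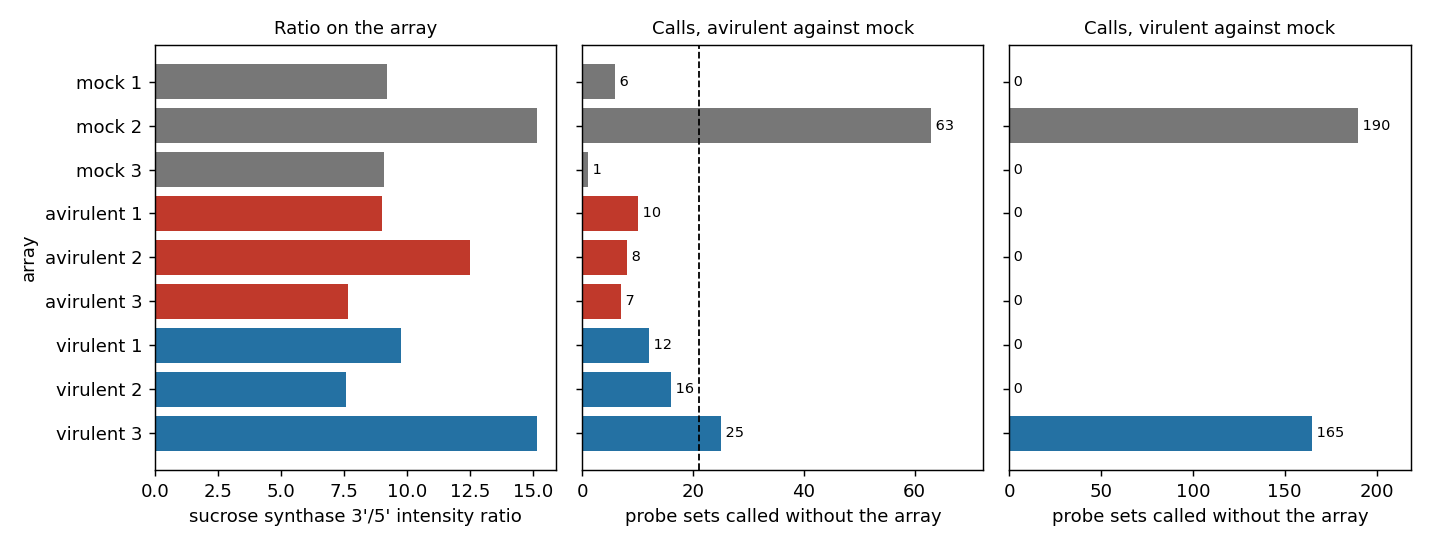
Bars per array, coloured by group, show the sucrose synthase 3′ to 5′ intensity ratio on the array (left) and the number of probe sets called when that array was left out, for avirulent against mock (middle) and virulent against mock (right). Dashed lines mark the counts with all arrays, 21 and 0. The right panel is at 0 except without mock 2 (190) and virulent 3 (165).

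Avirulent and virulent arrays were compared to find transcripts that differ between the incompatible and the compatible interaction. Between them 10 probe sets were called, 9 higher and 1 lower in the avirulent arrays, by 2.02-fold to 6.01-fold, and 3697 had an unadjusted p under 0.05, against 1835 expected by chance. The other 9 splits of these 6 arrays gave 588 to 3774, the highest being more than the real split. LOC543422 was the 1 called gene with a name, at 671 ± 64.7 in virulent arrays, 3.94-fold below the avirulent arrays (log2 fold change 1.98, SE 0.22, adjusted p = 0.022). Of the unnamed probe sets, the one with the largest difference was 6.01-fold higher in the avirulent arrays (554 ± 40 against 99 ± 49, adjusted p = 0.045), and the next was 5.07-fold higher (1616 ± 591 against 307 ± 33, adjusted p = 0.022). The 1 lower probe set, also unnamed, was 2.02-fold lower (1940 ± 181 against 3920 ± 341, adjusted p = 0.022). Over 22 alternatives LOC543422 was past the threshold in 16, the 6.01-fold probe set in 7, the 5.07-fold one in 17 and the lower one in 11.

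Further named genes did not pass, with adjusted p from 0.126 to 0.206 for 9 of them, 4 higher and 5 lower in the avirulent arrays. The higher ones were LOC543342 (log2 fold change 1.91), LOC543355 (0.63), LOC543492 (1.35) and LOC100037560 (1.43). The lower ones were LOC100125679 (-1.24), LOC542774 (-1.30), LOC606332 (-0.64), LOC542934 (-0.64) and LOC542814 (-0.68). PR5 had a log2 fold change of 2.15 (SE 0.53, adjusted p = 0.30), and it was again the 1 of 5 defence proteins that passed over the list alone.

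The photosynthesis list was higher in the avirulent than in the virulent arrays, in 24 of 26 probe sets and by a mean of 0.27 (camera, adjusted p = 0.0011). With an estimated correlation the call was lost (adjusted p = 0.52), and the range over 19 alternatives was 3.7e-06 to 0.52. The G-6-PDH difference was 0.61 to 1.14 on the avirulent and 1.07 to 1.61 on the virulent arrays, and with it as a covariate the list mean was 0.094 and the call was lost (adjusted p = 0.056). Here too the difference moved with the groups, so that fit cannot tell its part from that of the isolates. All 7 probe sets of PRK, PsbO, PsbP, petC and FBP were above 0, with a mean of 0.24. With 1 probe set per gene the list mean was 0.25 and the call stayed (camera, adjusted p = 0.00074). After quantile normalization the mean was 0.17 (adjusted p = 0.13), and without virulent 2 it was 0.19 (adjusted p = 0.070). The mean was 0.16 without avirulent 1, 0.47 without avirulent 3 and 0.43 without the filter on dim probe sets, and the call stayed in all 3. Median centring moved the median of all tested probe sets by -0.19, and the list mean was then 0.08 (adjusted p = 0.011). The 4 fructan exohydrolase probe sets, of 2 genes, were all lower in the avirulent arrays (mean -0.71), and 2 passed over the list alone, with 1-FEH (LOC543441) at -0.62 (adjusted p = 0.37). The remaining lists gave adjusted p of 0.14 (defence proteins, mean 0.61), 0.86 (redox enzymes, 0.06), 0.14 (histones, 0.26), 0.072 (tubulins, -0.14), 0.86 (translation genes, mean 0.19, median -0.02) and 0.86 (seed storage genes, -0.08). In alternatives, tubulins were called lower without the filter (adjusted p = 0.042), after median centring (-0.33, adjusted p = 0.013) and without virulent 1 (-0.20, adjusted p = 0.0056, range over 19 alternatives 0.0056 to 0.77), and histones higher without avirulent 3 (0.43, adjusted p = 0.047, range over 18 alternatives 0.047 to 0.84). Means were -0.17 for redox and detoxification, -0.02 for the fixed translation list and 0.12 for the dehydration genes. Their members with the smallest p did not pass over all probe sets: the thioredoxin Trx-M (LOC542973, 0.38), rbcl (0.76), wcH2A-9 (1.26, its others at -0.17 and 0.03), the beta-tubulin Tubb5 (LOC543261, -0.47, its other 3 between -0.06 and 0.02), RPS29 (1.66, the other at 0.22), BMY1 (-1.10), GSTZ1 (-0.45), eIF-2-beta (LOC543269, -0.12) and EM (0.36).

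Single arrays moved this count as well: it was 3 without mock 1, 39 without mock 2, 3 without mock 3, 0, 5 and 5 without avirulent 1, 2 and 3, 0 without virulent 1 or 2, and 35 without virulent 3. It was 30 without the 3 arrays of high sucrose synthase ratio and 3 after median centring. With the G-6-PDH difference as a covariate it was 0: the median size of the 10 log2 fold changes was 1.54 against 1.91, with a median SE of 0.28 against 0.22, while the lower probe set stayed at -1.03 with an SE of 0.17 against 0.12. Because that difference moved with the groups, this fit cannot tell its part from that of the isolates.

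**Figure D3:**
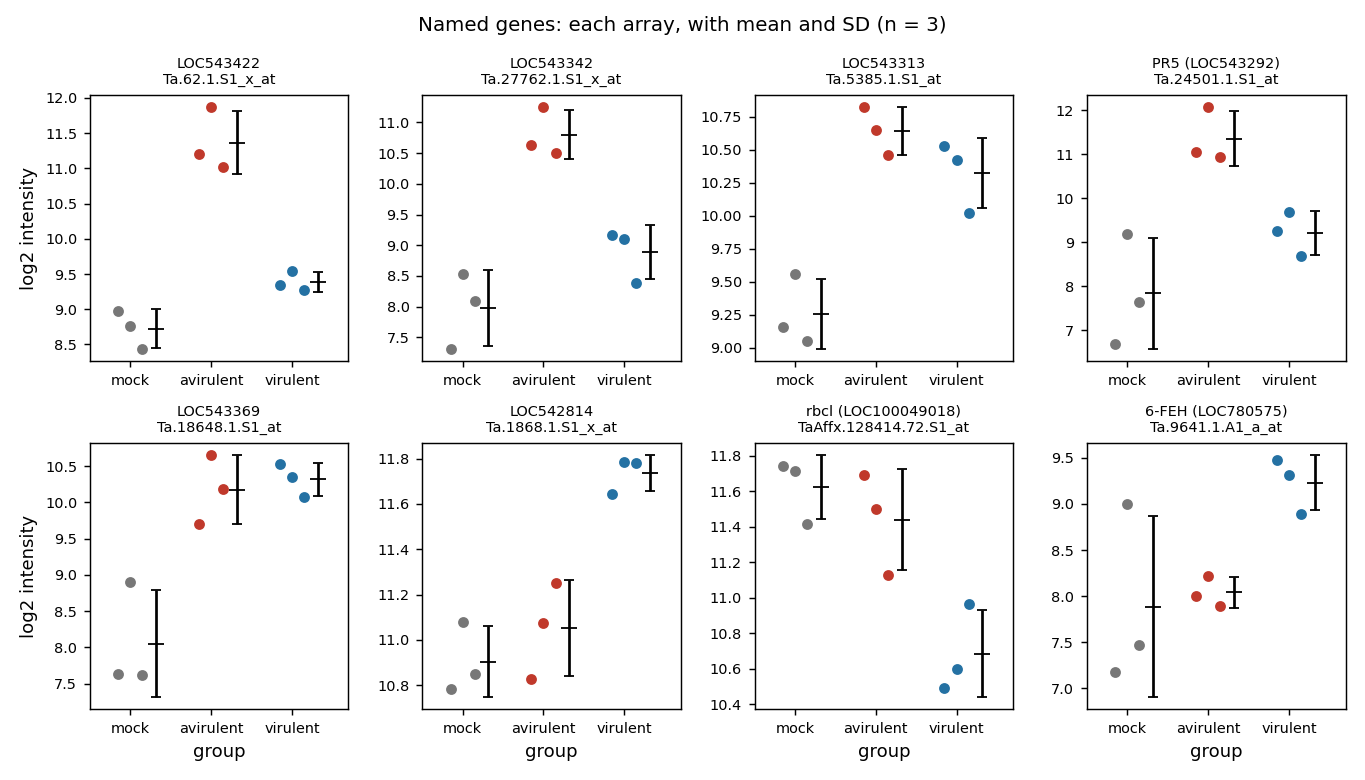
Log2 intensity of 8 named genes on each array (points), with the mean and SD of each group of 3 arrays (bars). The first 3 genes were called between avirulent and mock arrays, the others were not called; mock 2 is the middle grey point and lies highest of the mock arrays in 6 of the 8 genes, all but LOC543422 and rbcl.

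Across all 3 groups, the F test called 19 probe sets, 17 of them highest in the avirulent arrays, and 14 of the 19 were among the 21 called between avirulent and mock. In LOC543422 and LOC543342 the virulent arrays averaged 671 ± 64.7 and 488 ± 133, between the means of the mock and the avirulent arrays. Among the 21 probe sets called in the avirulent arrays, 19 were also higher in virulent than in mock arrays, 11 of them with an unadjusted p under 0.05 in limma. Their median fold change was 1.43 in the virulent and 3.98 in the avirulent arrays. All 21 were higher in avirulent than in virulent arrays, 20 with an unadjusted p under 0.05 and 5 past the adjusted threshold. These probe sets were chosen by their difference between avirulent and mock arrays, and those arrays enter the other comparisons too. In 50 simulations with that difference kept and virulent arrays like mock, 51.3% of the called probe sets were higher in virulent than in mock arrays, 7.27% with an unadjusted p under 0.05 and with a median fold of 1.01, and 95.8% were higher in avirulent than in virulent arrays. With virulent arrays like avirulent ones, 48.7% were. The 21 probe sets were not independent: mock 2 was the highest mock array in 15 of them, and virulent 3 the lowest virulent array in 15. A shift shared by the probe sets of an array could move many of them together. The 19 of 21 therefore carries less weight than 21 separate changes would. The F count was 4, 166 and 2 without mock 1, 2 and 3, 0, 4 and 3 without avirulent 1, 2 and 3, 0, 1 and 92 without virulent 1, 2 and 3, and 247 without the 3 arrays of high sucrose synthase ratio.

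The overlap of the calls of both infections was 0, since 0 probe sets were called in the virulent arrays, and the overlap of independent lists of these sizes is 0. Over all tested probe sets, the fold changes of both infections against mock had a correlation of 0.43, against 0.50 in simulations without any effect that shared the mock arrays, and the same sign in 62.5% against 66.7%. Their covariance was 0.0619 against 0.0548. Those simulations drew all arrays independently. With mock and avirulent arrays of the same number correlated as their deviations were, the simulated values were 0.44, 64.4% and 0.0420, so the correlation and the share of equal signs exceeded neither simulation, while the covariance exceeded both (SD over simulations 0.00099 and 0.00085, with probe sets drawn independently). With the mock arrays split so that 1 infection had 1 of them and the other the remaining 2, a check chosen after these values were seen, the correlation was -0.10 to 0.13 over the 6 ways, the covariance -0.0243 to 0.0246 and the share of equal signs 46.4% to 55.4%. These values are across genes, which are not independent replicates, and part or all of the relation over shared mock arrays may come from that sharing.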

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

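The test of array scaling, the count of deviating arrays and every fit that uses the sucrose synthase or G-6-PDH controls were chosen after the counts had been seen. A direct test found 10 probe sets whose levels differed between the 2 infections. The mock arrays entered that test only through the estimate of the spread. The named gene among them, LOC543422, was 1.98 higher on the log2 scale in the avirulent arrays. The unnamed probe set with the largest difference was 2.59 higher there, and it was below mock in the virulent arrays (-1.65) without passing. The next unnamed one was 2.34 higher, with the virulent arrays at the level of mock (-0.01). The 1 lower probe set, also unnamed, had a log2 fold change of -1.02. Of the 10 splits of these 6 arrays into 3 and 3, 1 (the real one) gave as many as 10 calls and the highest other gave 0, but 10 splits are too few for a share under 0.05. Over 22 alternatives LOC543422 kept its call in 16, the probe set at 2.59 in 7, that at 2.34 in 17 and that at -1.02 in 11, and with the G-6-PDH covariate 0 of the 10 were past the threshold (LOC543422 at 1.55, SE 0.27, against SE 0.22 without it). That covariate moved with the groups, so the fit cannot tell its part from that of the isolates.

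Every probe set called between avirulent and mock arrays, LOC543422, LOC543342 and LOC543313 included, was higher in the avirulent arrays, but 14 of 46 calls were lower in the fit of these 6 arrays with the replicate block, and 16 of 82 without the 3 arrays of high sucrose synthase ratio. The scaling of the arrays as the cause is argued against by 20 of the 21 staying past the threshold after quantile normalization. A linear trend with RNA integrity is argued against by a median log2 fold change of 2.02 with the sucrose synthase covariate and 1.99 with the G-6-PDH covariate, against 1.99 without. Both measures overlapped between these groups, so the fits had little room to move that value, and the argument rests on this overlap. The log2 differences for sucrose synthase were 3.18 to 3.92 on mock and 2.93 to 3.64 on avirulent arrays. Those for G-6-PDH were 0.60 to 0.85 and 0.61 to 1.14. Rust transcripts that bind wheat probes stay open: the median was 0.52 in the virulent arrays, and without a measure of fungal RNA per sample this cannot be told apart from a wheat response. Of the 10 splits of the 6 arrays, 1 (the real one) gave as many as 21 calls and the highest other gave 2, but 10 splits are too few for a share under 0.05. Among the 4 splits that part all same-numbered arrays the highest other gave 0. All these counts are from fits without the replicate block. With the block the real groups gave 24 calls, and no such count is given for the other splits. A wheat response to recognition of the avirulent isolate is the biological explanation that the design names, and it stays open as well.

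Between virulent and mock arrays 0 probe sets were called, but leaving out either of 2 arrays, mock 2 (190 calls) or virulent 3 (165 calls), raised the count above 100. That there are 2 such arrays is part of the pattern and tests nothing about its source. For an exchange of the labels of these arrays, over 100 calls were predicted with the labels exchanged, and 0 were found. The labels as given also led to 0, so this count alone cannot decide. With the labels exchanged 2107 probe sets had a limma unadjusted p under 0.05, against 3771 with the labels as given. With the sucrose synthase difference as a covariate 0 probe sets were called, which argues against a linear trend with that measure of RNA integrity as the whole cause; both arrays do have the highest ratios (15.2), 71 probe sets followed that measure within groups, and an effect of another form stays open. The real split gave 0 calls and the highest other of the 10 splits 1; every count is at least 0 and the splits are too few for a share under 0.05, so they test nothing here. A weaker or later response in single samples is a biological explanation that was not tested.

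The first principal component, with 24.1% of the variance, split the arrays across the groups, with mock 3, avirulent 3 and virulent 2 at one end and avirulent 1, mock 2 and avirulent 2 at the other. Over the 9 arrays it had r = -0.58 (rho = -0.47) with the sucrose synthase difference (exact two-sided permutation p = 0.104, rho p = 0.213). With the median log2 intensity it had r = -0.80 (rho = -0.80, exact permutation p = 0.0136, rho p = 0.0138). The component and that median come from the same log2 intensities, with no centring of the arrays, so part of the second relation may be built in. The adjusted values over these 2 relations were 0.104 and 0.0272. Without the 2 arrays farthest from the median, r was -0.62 in both (exact permutation p = 0.137 and 0.144), so the second relation was no longer past 0.05 on the 7 arrays left without mock 2 and avirulent 1, and neither measure can be told apart from another source with so few arrays. For the F test, 3 of 100 splits of the 9 arrays into 3 groups of 3 (the real one and 99 others drawn, of 280 in all) gave as many as the real 19 calls, a share under 0.05. The highest other gave 76 calls, with mock 3, avirulent 3 and virulent 2 as one of its groups and avirulent 1, mock 2 and avirulent 2 as another, so the arrays hold a structure along this component that is not the treatment. The splits were drawn without regard to replicate numbers, and the share does not allow for pairs. The split with 76 calls joined 2 mock and avirulent pairs of the same number, whose deviations correlated at 0.19 and 0.39. No biological explanation of it was tested.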

How the results depend on the processing

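Alternatives that use the sucrose synthase or G-6-PDH controls, the blocked fit of 6 arrays and, for the lists, median centring and each replicate left out were chosen after seeing the data. No alternative turned the direction of a called gene, and LOC543422 kept its call between avirulent and mock in 22 of 23 alternatives, LOC543342 in 19 and LOC543313 in 14. The calls of avirulent against mock, against 21, were 0 without the intensity trend, 68 with array weights (5 lower), 9 with only the groups compared, 42 at an adjusted p under 0.10, 13 with adjustment over the 3 comparisons, 46 with the sucrose synthase covariate (4 lower), 82 without the 3 arrays of high ratio (16 lower) and 46 with the replicate block on 6 arrays (14 lower); the block on 9 arrays gave 24. Those of virulent against mock, against 0, were 321 without those 3 arrays, 1 with the G-6-PDH covariate and 0 elsewhere except for single arrays. Those of avirulent against virulent, against 10, were 3 after median centring, 0 without the trend, 28 with only the groups compared, 2 with the replicate block, 0 with the G-6-PDH covariate and 30 without the 3 arrays. The F test, against 19, gave 0 without the trend, 73 with array weights, 32 at an adjusted p under 0.10 and 247 without the 3 arrays, and the overlap of both infections was 54 without them. List calls, against 2, were 0 with an estimated correlation, 0 with fry, 0 after quantile normalization, 1 with the G-6-PDH covariate and 4 after median centring. With single replicates left out, counts ranged from 1 (mock 3) to 63 (mock 2) for avirulent against mock, 0 to 190 (mock 2; 165 without virulent 3) for virulent against mock, 0 (avirulent 1, virulent 1 and virulent 2) to 39 (mock 2; 35 without virulent 3) for avirulent against virulent, 0 to 166 (mock 2) for the F test, 0 to 34 (mock 2) for the overlap and 0 (virulent 2) to 3 for the lists. Fits without an array have fewer residual degrees of freedom; the cause was not tested for the other changes. Of 1467 values of named genes and probe sets, 1334 kept direction and side of the threshold, 63 lost and 68 gained a call, and 2 that were never called turned: a probe set of 6-FEH (LOC780575) ranged from -0.029 (without avirulent 1) to 0.46 in avirulent against mock, and 1 of Rab15 (LOC543293) from -0.75 to 0.30 (without virulent 1) in virulent against mock. Same-numbered arrays of the virulent group stayed below the limit for pairs; between avirulent and virulent arrays the block ended the calls of the 6.01-fold higher and of the 2.02-fold lower unnamed probe set (adjusted p = 0.091 in both, ranges 0.019 to 0.42 and 0.013 to 0.38). On all 9 arrays the block changed no other count by over 1.5 times, but between avirulent and mock it ended 4 of the 21 calls, a second probe set of LOC543422 among them, and added 7, with PR5 and LOC543369 among them; in fits of the 6 mock and avirulent arrays it moved the count from 9 to 46. It changed no call of a gene list. Signal over background limits what dim probe sets can show, and no detection calls were used: 15 were called between avirulent and mock with no filter and 26 with the stricter one, but a filter also changes the number of tests and the trend, which were not told apart.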

Other observations

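The values in this part were looked at only after the comparisons had been made. Among the genes with a descriptive name, several passed between virulent and mock arrays in fits that left out 1 array, and not with all arrays. Without mock 2, GLU1A (LOC780595) had a log2 fold change of 1.64 (limma adjusted p = 0.0063), 6-FEH (LOC780575) 1.90 (adjusted p = 0.010) and 1 probe set of TUBA 1.18 (adjusted p = 0.027). Without virulent 3, 1 probe set of rbcl had -1.08 (adjusted p = 0.037), XTH -1.53 (adjusted p = 0.037) and 1 probe set of RPS29 (LOC606342) -2.57 (adjusted p = 0.021). With all arrays the other probe set of RPS29 was at 0.0021 and that of TUBA at 0.08, beside -1.76 and 0.84 for these. On all arrays the adjusted p of the 6 probe sets lay between 0.26 and 0.38. Of the 190 probe sets called without mock 2, 169 were higher in the virulent arrays. Of the 165 called without virulent 3, 122 were lower. The 2 sets shared 22 probe sets, all with the same direction. Both fits kept mock 1, mock 3, virulent 1 and virulent 2, so the equal direction was all but given and tests nothing.

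In the 21 probe sets called between avirulent and mock arrays, mock 2 was the highest of the mock arrays in 15 and virulent 3 the lowest of the virulent arrays in 15. Mock 2 exceeded the mean of the other mock arrays by a median of 0.40 on the log2 scale over these probe sets, against 0.04 over all tested ones. Virulent 3 differed from the other virulent arrays by a median of -0.28, against 0.00 over all. PR5 shows both, at an intensity of 588 on mock 2 against 103 and 199 on the other mock arrays, and at 414 on virulent 3 against 611 and 820 on the other virulent arrays. The replicates have no order, and the arrays were not regrouped by these values. When 1 array of each group was left out, in 27 combinations, the calls between virulent and mock were 270 to 410 in those without both mock 2 and virulent 3, and at most 76 in the other 24.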
